A study of Mus musculus with 2 samples.

How the data were processed

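Total RNA of mouse erythroblasts, the nucleated precursors of red blood cells, was sequenced in 2 libraries. Per the labels, these were primary cells of adult male C57BL/6J mice aged 5 to 6 weeks. Each library was made from 1 ng of RNA with spike-in RNA added, and the labels give its fragment size range, without a unit, as 150 to 400. The labels number the libraries as biological replicates 1 and 2 and give them separate biosamples under a single donor entry. They do not say whether the cells came from separate animals. Both libraries form 1 group, and the design holds no second condition.

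Each library came with a table per gene and a table per transcript. Per the deposited read-me, the tables were quantified from a transcriptome alignment on the mm10 assembly with the annotation GENCODE M4. The columns are those that RSEM writes, but the aligner, the quantifier and their versions are not given in the sources used here. The deposited expected counts are estimates of reads per feature in which reads that match several places are shared out, so they need not be whole. The deposited TPM values (transcript abundance scaled to a fixed total) were scaled by the authors over all rows of a table, mitochondrial rRNA and spike-ins included. FPKM values (fragments scaled by length and library size), per the file headers, served only as an alternative unit. The posterior mean of TPM, a score deposited beside the maximum likelihood TPM, served as an alternative estimate. The percent of a gene's TPM carried by each transcript was also deposited. Shares computed from the rounded TPM of detected genes differed from it by at most 0.783 percentage points in replicate 1. The deposited bounds of the TPM intervals are not reported here.

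The tables held 43346 gene rows. Of these, 42462 were matched by Ensembl identifier without its version to GENCODE M21, a later release on the same build, which gave symbols, gene types, coordinates and transcript names. The 884 rows without a match held 0.0126% and 0.0124% of the gene counts. A further 26248 rows carried a number in place of an Ensembl identifier, had lengths of 61 to 259 bases and 0 counts in both libraries, and were left out. The 97 spike-in rows were left out of all gene results. The listed symbols Hbb-b1, Hbb-b2, Ahsp, Rn7sl1 and Snhg1 were not matched and were not analysed here. Erfe was matched through its older symbol Fam132b.

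The libraries held 80806663 and 117032607 expected counts. Nuclear protein-coding genes took 5.44% and 5.82% of these, which is the depth behind most values given here. A count of 0 allows up to 3 counts, equal to a TPM of 0.0482 in replicate 1 and 0.0333 in replicate 2 for a transcript of 1 kb. Reads without molecular identifiers are not independent molecules, so such limits cover counting error only.

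The gene lists, the rule for named genes, the definitions of the results and most alternatives were fixed before the data were examined. The rule named all globin genes, and from each other list up to 6 members with the highest and up to 2 with the lowest mean TPM. It also named the 10 genes with the highest mean TPM, and the 5 genes with the largest ratio between the libraries in each direction among genes with a mean of at least 100 rounded counts. It further named isoform genes whose leading transcript differed between the libraries or held under 60% of the TPM. Some genes that the rule names are not reported here. A gene was called detected at a TPM of 1 or more in both libraries. Values are the mean ± SD of n = 2 libraries.

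With 1 group there was no test between conditions, and no p-value is given. Agreement was described by Pearson and Spearman correlation of log2(TPM + 1) across detected genes, which are not independent replicates, with an interval from 1000 bootstrap draws of genes. Expected counts were rounded to whole numbers for edgeR 4.0.16, which gave TMM factors (0.962 and 1.04) and a common dispersion under an intercept-only design, over the 10012 genes kept by its expression filter. DESeq2 1.42.0 gave alternative size factors. A chi-square test of the rounded counts of 11414 genes with at least 20 summed counts checked for a single library deposited in duplicate; it takes reads as independent and sets the libraries against counting noise alone. The log2 ratio of list medians used a pseudocount of 0.1. For each list with at least 4 members of 20 or more summed reads, the median log2 ratio of the libraries (log2 of TMM-scaled counts per library total, prior count 2) was placed among 10000 random lists, each member drawn from genes within 100 ranks of mean expression. A list was called apart below percentile 2.5 or above 97.5, where chance puts 5% of lists if their genes vary independently of each other. Each list's median TPM was also placed among 10000 random lists of protein-coding genes of the same size.

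These steps were tested on simulated counts for the comparison of the 2 erythroblast libraries, with 43346 genes drawn and 11444 entering the list step. A simulated coefficient of variation of 0.2 was recovered as 0.213, and a log2 ratio of 1 in 200 genes as a median of 1.03. Of 200 lists of 12 changed genes, 100% were called apart, and of 200 lists of 12 unchanged genes 3%. That ratio is larger, and that coefficient smaller, than in the data. The coefficient of the data (33.5%) was then given to every gene, although spread in the data was narrower at greater depth. Over 11414 genes, the members of each list called apart were shifted by its distance from the median of its random lists. The log2 shifts were 0.0871 for ribosomal proteins, -0.348 for cell cycle regulators and -0.138 for noncoding RNAs. Of 200 runs per list, 16%, 30% and 9.50% were called apart, in that order. Without a shift these were 4.50%, 4% and 3.50%. This simulation was added after seeing the data.

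Alternatives changed the detection threshold, the unit, the estimate of abundance, the gene set behind the scaling, the pseudocount, the filter on low values, the prior count, the summary, the scaling factors or the libraries used. A count was called moved beyond 1.5 times, a mean beyond 1 SD, a correlation outside its bootstrap interval, a share of genes outside its 95% Wilson interval, and the dispersion beyond 1%. Rescaling to nuclear protein-coding genes, leaving out the neutrophil and monocyte markers, the comparison over genes detected in either library, and the alternatives for single named genes were chosen after seeing the data. Pseudogene transcripts were aligned to mitochondrial transcripts with blastn 2.17.0 at an E-value limit of 1e-10. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.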

Results

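Total RNA-seq profiled primary erythroblasts of adult male C57BL/6J mice in 2 libraries of 1 group. Replicate 1 held 80806663 expected counts and replicate 2 held 117032607. The account covers which genes the cells expressed, how closely the libraries agreed, and which transcripts led each gene. Values are the mean ± SD of n = 2 libraries unless a replicate is named, and coordinates are on mm10.

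Ribosomal RNA of the mitochondrion dominated the quantified genes of both libraries. Its genes mt-Rnr2 and mt-Rnr1 led all genes at 422964 ± 8068 and 360905 ± 6173 TPM, and together took 78.3% of TPM in replicate 1 and 78.5% in replicate 2. Mitochondrial mRNAs took 8.08% and 8.24%. Among them, mt-Co1, a cytochrome oxidase subunit, stood at 24515 ± 929 TPM, the ATP synthase genes mt-Atp8 and mt-Atp6 at 22085 ± 244 and 13659 ± 556 TPM, and mt-Nd4 of complex I at 4003 ± 248 TPM. The noncoding gene Gm42418 (chromosome 17, 39846958 to 39848788) stood at 40793 ± 9091 TPM, and 68.0% of its span overlaps the annotated rRNA-related gene Rn18s-rs5. The nuclear pseudogene Gm29216, which matches mt-Co1 at 99.8% identity and may share its reads, stood at 22153 ± 1622 TPM. With the globin genes Hbb-bs and Hba-a2, these were the 10 most abundant genes. The 10 highest features of each library took 92.8% and 92.4% of TPM, and nuclear protein-coding genes as a whole took 4.68% and 5.10%. Genes typed as rRNA outside the mitochondrion held 2 and 8.66 counts, so the share of cytoplasmic rRNA cannot be read from these values.

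In all, 3464 genes, 3133 of them protein coding, were detected at a TPM of 1 or more in both libraries. By reads, 9988 genes held at least 10 expected counts in both. Rescaled to nuclear protein-coding genes, an alternative chosen after seeing the data, 9210 genes reached a rescaled TPM of 1 in both. These genes held 4.68% and 5.10% of TPM, so that cut is far lower in deposited TPM. In replicate 1 it lies near the 0.0482 TPM that a count of 0 allows for a transcript of 1 kb. Some of the 9210 genes may thus not differ from no signal.

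Adult globin genes were the most abundant nuclear protein-coding genes. The beta-globin genes Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096) and Hbb-bt (ENSMUSG00000073940, chromosome 7, 103812524 to 103813996) stood at 7310.4 ± 698 and 3611 ± 274 TPM. The alpha-globin genes Hba-a2 (ENSMUSG00000069917, chromosome 11, 32296489 to 32297298) and Hba-a1 (ENSMUSG00000069919, chromosome 11, 32283511 to 32284465) stood at 7301 ± 206 and 3075 ± 26.0 TPM. Together they took 2.13 ± 0.121% of all TPM and 43.6 ± 0.203% of the TPM of nuclear protein-coding genes. Alpha globin summed to 10377 ± 232 TPM and beta globin to 10921 ± 972 TPM. The log2 ratio of alpha to beta was -0.07 ± 0.10, a difference smaller than the spread between the libraries. It was -0.26 in counts scaled to the library total, which carry no length correction. The paralogs of each chain share reads, so the split within a chain is uncertain.

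Embryonic globins, which red cells of the early embryo use, were close to the limit of the data. Hba-x stood at 0.420 ± 0.0566 TPM and Hbb-y at 0.280 ± 0.212 TPM. Hbb-bh1 and Hbb-bh2 had 0 expected counts in both libraries, which allows up to 3 counts each. Together, embryonic genes took 0.00249% of globin TPM in replicate 1 and 0.00402% in replicate 2.

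Heme synthesis genes were expressed throughout. All 10 listed members were detected, with a median of 19.7 ± 0.0530 TPM. Alas2, the first enzyme of erythroid heme synthesis, led at 179 ± 5.54 TPM, with the iron-inserting enzyme Fech at 44.3 ± 2.34 TPM and Urod at 37.4 ± 0.870 TPM. Ppox and Cpox stood at 21.8 ± 0.262 and 17.6 ± 0.368 TPM. The lowest were Slc25a38 at 6.32 ± 3.06 TPM and Alad at 5.73 ± 0.346 TPM.

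Of 12 iron genes, 5 were detected. Slc25a37, an iron carrier of the mitochondrial inner membrane, stood at 174 ± 2.27 TPM and the transferrin receptor Tfrc at 93.5 ± 5.76 TPM. The ferritin genes Ftl1 and Fth1 stood at 76.7 ± 11.1 and 52.9 ± 2.67 TPM, and the iron exporter Slc40a1 at 5.52 ± 1.63 TPM. The importer Slc11a2 stood at 0.825 ± 0.177 TPM, the carrier Slc25a28 at 0.215 ± 0.0778 TPM and the hormone gene Erfe at 0.0800 ± 0.0849 TPM.

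Membrane and skeleton genes of the red cell were detected for 18 of 20 members, with a median of 17.6 ± 0.470 TPM. The anion exchanger Slc4a1 (chromosome 11, 102348824 to 102366203) stood at 259.6 ± 0.658 TPM, the blood group protein Kel at 139 ± 0.396 TPM and the skeletal protein Epb41 at 82.2 ± 1.52 TPM. Epb42 stood at 58.0 ± 0.559 TPM and Ermap at 50.5 ± 2.40 TPM. Icam4 and the glucose transporter Slc2a1 were lowest at 0.965 ± 0.346 and 0.0650 ± 0.0636 TPM.

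All 11 matched genes of red cell enzymes and antioxidants were detected. The glutathione peroxidase Gpx1 stood at 264 ± 23.6 TPM, the carbonic anhydrases Car2 and Car1 at 112 ± 7.61 and 26.6 ± 5.40 TPM, and the peroxiredoxin Prdx2 at 66.2 ± 12.6 TPM. Bpgm, whose product tunes oxygen release from hemoglobin, stood at 32.9 ± 2.23 TPM and the catalase gene Cat at 25.6 ± 1.03 TPM. Hagh and the pyruvate kinase Pklr were lowest at 10.3 ± 1.90 and 1.15 ± 0.0354 TPM. All 12 genes of organelle clearance and enucleation were detected. Ube2l6 led at 49.3 ± 3.83 TPM, with Xpo7, a nuclear export receptor, at 43.4 ± 3.39 TPM, Tent5c at 31.9 ± 0.311 TPM, the mitophagy receptor Bnip3l at 30.1 ± 0.0354 TPM, Arl4a at 28.4 ± 1.65 TPM and the ubiquitin ligase Ube2o at 24.6 ± 2.73 TPM. Fbxo7 and Mxi1 were lowest at 4.84 ± 0.601 and 2.56 ± 0.226 TPM.

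Erythroid transcription factors had a median of 3.89 ± 0.290 TPM, with 13 of 17 detected. Lmo2 led at 41.3 ± 2.48 TPM, then Nfe2 at 23.1 ± 2.21 TPM, Sox6 at 22.2 ± 1.98 TPM, E2f2 at 11.8 ± 0.0212 TPM, E2f4 at 10.1 ± 0.212 TPM and Klf3 at 8.79 ± 1.83 TPM. Cbfa2t3 and Zbtb7a were lowest at 0.865 ± 0.177 and 0.615 ± 0.0212 TPM. Chosen after their values were seen, the erythroid regulators Tal1, Gata1 and Klf1 stood at 4.21 ± 0.410, 3.17 ± 1.30 and 2.98 ± 0.212 TPM. In erythropoietin signalling, 6 of 12 members were detected. The survival gene Bcl2l1 led at 28.0 ± 0.580 TPM, the kinase Pim1 stood at 7.72 ± 0.0919 TPM and the receptor Epor at 3.36 ± 0.269 TPM. Ptpn6, Lyn and Jak2 stood at 2.95 ± 0.0919, 2.04 ± 0.382 and 1.98 ± 0.0212 TPM. By the posterior mean Ptpn6 stood at 5.43 TPM. The feedback inhibitor Socs3 had 3 reads in each library, and Socs2 had 1 in replicate 1 and 0 in replicate 2.

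Cell cycle genes were expressed, led by Mki67, a marker of cycling cells, at 43.2 ± 2.08 TPM. Of 13 genes of G2 and M phase, 11 were detected, among them Top2a at 7.09 ± 0.283 TPM, Birc5 at 4.91 ± 0.806 TPM, Cenpe at 3.67 ± 0.396 TPM, Ccnb2 at 3.66 ± 0.00707 TPM and Ccnb1 at 3.33 ± 0.382 TPM. Cdk1 and Aurka were lowest at 1.18 ± 0.339 and 1.13 ± 0.184 TPM. Of 13 S phase genes, 10 were detected, led by the replication clamp Pcna at 15.8 ± 1.43 TPM, with Rrm2 at 6.41 ± 0.728 TPM, Mcm3 at 6.40 ± 0.191 TPM, Slbp at 6.29 ± 0.559 TPM, Mcm6 at 4.56 ± 1.59 TPM and Mcm7 at 4.48 ± 1.05 TPM. Mcm5 and Cdc6 were lowest at 1.08 ± 0.148 and 1.01 ± 0.0566 TPM. Of 13 cell cycle regulators, 7 were detected. The inhibitor Cdkn1b led at 12.9 ± 0.898 TPM, followed by the cyclins Ccna2 and Ccnd3 at 6.48 ± 0.891 and 5.01 ± 0.771 TPM, Cdk4 at 4.27 ± 0.0636 TPM, Ccne1 at 1.98 ± 1.39 TPM and Cdkn2d at 1.89 ± 0.410 TPM. Ccnd1 stood at 0.0450 ± 0.00707 TPM and Cdkn1c had 0 counts in both libraries.

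Replication-dependent histones were detected for 37 of 67 genes. The linker histone Hist1h1e led at 72.3 ± 1.80 TPM, then Hist1h4d at 49.5 ± 1.51 TPM, Hist1h1b at 25.5 ± 0.127 TPM, Hist1h2bn at 16.9 ± 5.25 TPM, Hist2h3b at 16.9 ± 1.12 TPM and Hist1h2bk at 13.3 ± 3.47 TPM, while Hist1h2aj and Hist1h3h had 0 counts in both libraries. The ribosomal protein list was taken by symbol: protein-coding genes beginning with Rpl or Rps and a digit, Rplp0 to Rplp2, and Rpsa. That rule admits genes that do not encode ribosomal proteins, and it took in Rpl9-ps1 and Rpl36-ps4, both at 0 TPM. Of its 102 members, 85 were detected. The list had a median of 20.6 ± 2.18 TPM, led by Rps2 at 72.8 ± 18.0 TPM and Rps12 at 61.6 ± 15.3 TPM. All 12 housekeeping genes were detected, from Eef1a1 at 202 ± 19.9 TPM and Actb at 109.9 ± 3.74 TPM to Sdha at 2.64 ± 0.318 TPM and Tbp at 2.43 ± 0.424 TPM. Of 7 nuclear and structural noncoding RNAs, 6 were detected. Rn7sk, Rpph1 and Rmrp stood at 1761 ± 252, 812 ± 42.8 and 530.2 ± 78.2 TPM, Malat1 at 599 ± 33.8 TPM, Gas5 at 29.4 ± 5.61 TPM and Neat1 at 4.57 ± 0.368 TPM, while Terc had 1 and 2 reads. Y-linked Eif2s3y and Ddx3y stood at 3.49 ± 0.262 and 2.33 ± 0.573 TPM, and Uty and Kdm5d at 0.990 ± 0.113 and 0.785 ± 0.502 TPM. Xist, expressed from the inactive X of female cells, had 1 count in replicate 1 and 0 in replicate 2.

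**Figure D1:**
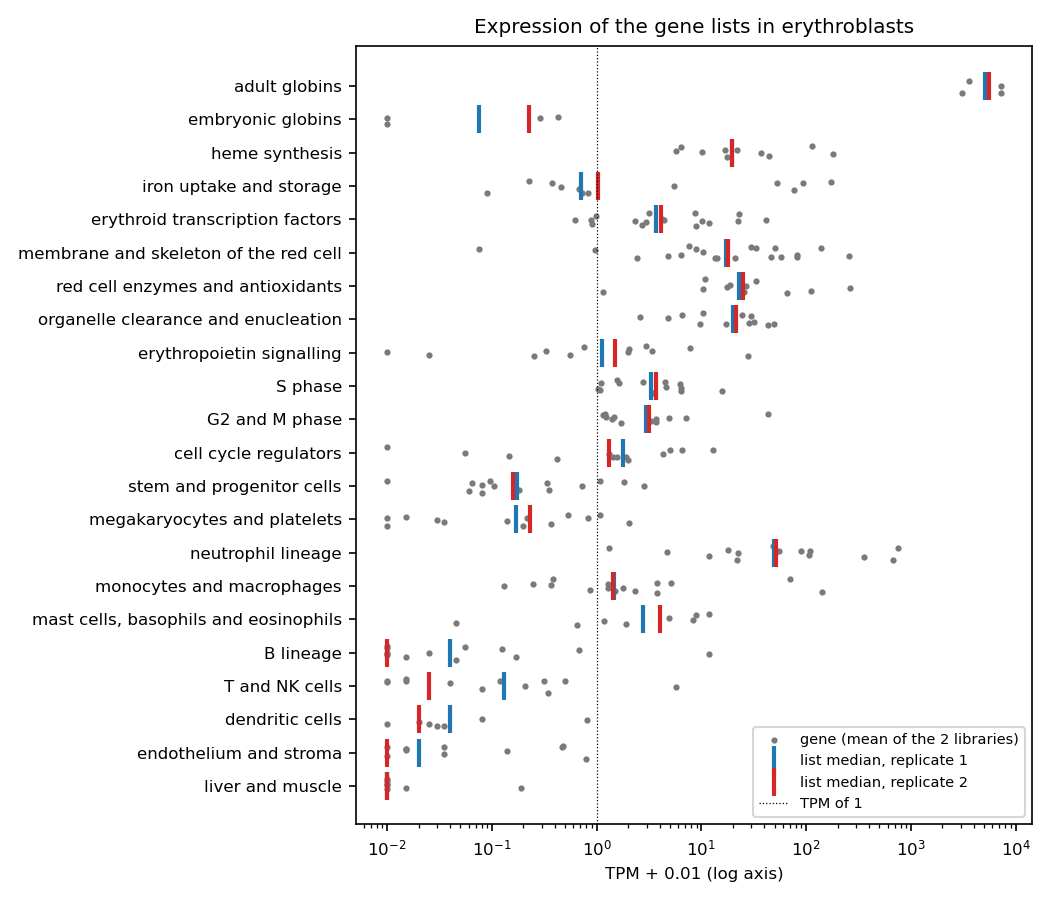
Expression of the fixed gene lists, with TPM + 0.01 on a log axis; each grey point is a gene (mean of the 2 libraries), and the blue and red bars are the list medians of replicates 1 and 2. The neutrophil list has a median of 50.5 ± 0.813 TPM, above that of heme synthesis at 19.7 ± 0.0530 TPM, and the dotted line marks a TPM of 1.

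Transcripts of the neutrophil lineage were abundant beside the erythroid ones. All 15 listed neutrophil genes were detected, with a median of 50.5 ± 0.813 TPM against 13.8 ± 0.346 TPM over the 58 pooled genes of the heme synthesis, erythroid transcription factor, membrane and skeleton, and red cell enzyme lists. Globins, iron genes, erythropoietin signalling and organelle clearance are not in that pool. The calcium-binding proteins S100a9 (chromosome 3, 90692632 to 90695721) and S100a8 (chromosome 3, 90668978 to 90670035) stood at 747 ± 118 and 678 ± 88.0 TPM. Their sum was 5.49 ± 0.807 times the level of Slc4a1. Ngp, Lcn2, Camp and Mpo, which encode granule proteins, stood at 356 ± 2.90, 108 ± 0.905, 108 ± 6.29 and 88.5 ± 4.65 TPM, while Mmp8 and the regulator Cebpe were lowest at 4.72 ± 0.375 and 1.31 ± 0.332 TPM. The list summed to 10.9 ± 0.436% of the TPM of the adult globins. Among monocyte and macrophage genes, 10 of 15 were detected, led by Lyz2, which neutrophils also express, at 142 ± 10.97 TPM and by Ly6c2 at 70.5 ± 12.2 TPM. Vcam1, Ccr2, C1qb and Cd68 stood at 5.12 ± 0.0849, 3.80 ± 0.0849, 3.77 ± 0.898 and 2.29 ± 0.354 TPM, with Timd4 and Cd14 lowest at 0.235 ± 0.177 and 0.120 ± 0.0566 TPM.

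Of 8 genes of mast cells, basophils and eosinophils, 5 were detected, among them the basophil protease Mcpt8 at 11.9 ± 2.14 TPM, Prg2 at 8.79 ± 2.12 TPM, Prss34 at 8.35 ± 0.742 TPM and Cpa3 at 4.89 ± 2.05 TPM. Few genes were detected in the lists of other lineages. Of 13 B lineage genes, 1 was detected, Ighm at 11.9 ± 0.417 TPM, while Cd79b, Dntt and Blnk stood at 0.675 ± 0.233, 0.160 ± 0.170 and 0.115 ± 0.0495 TPM. All immunoglobulin constant genes, Ighm among them, summed to 114 TPM in replicate 1 and 133 in replicate 2, and variable genes to 98.1 and 109. Of 12 T and NK cell genes, 1 was detected, Nkg7 at 5.76 ± 0.976 TPM, and Cd3d and Cd8a had 0 counts. None of the 7 dendritic cell genes, 11 endothelial and stromal genes or 7 liver and muscle genes was detected. The highest of these lists were Irf8 at 0.805 ± 0.148 TPM, Lepr at 0.790 ± 1.12 TPM from 47 reads in replicate 1 and 0 in replicate 2, and Acta1 at 0.180 ± 0.127 TPM. Stem and progenitor genes were detected for 3 of 14 members, with Cd48, Myc and Kit at 2.82 ± 0.453, 1.82 ± 0.297 and 1.06 ± 0.0849 TPM. Megakaryocyte and platelet genes were detected for 1 of 13 members, Itga2b at 2.05 ± 1.30 TPM, while Pf4 and Vwf stood at 1.08 ± 0.177 and 0.820 ± 0.0707 TPM.

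The pooled erythroid lists exceeded the 81 pooled markers of other lineages by a log2 ratio of medians of 4.78 ± 0.38. These markers are the neutrophil, monocyte, B lineage, T and NK, mast cell, dendritic, and endothelial and stromal lists, without the stem, megakaryocyte, and liver and muscle lists. Of the erythroid genes, 52 of 58 were detected, against 32 of 81 markers with a median of 0.415 ± 0.120 TPM. The log2 ratio was 3.39 with a pseudocount of 1 and 6.81 without the neutrophil and monocyte markers, the latter chosen after seeing the data. Against random lists of protein-coding genes of the same size, the medians of the heme synthesis, neutrophil and monocyte lists lay at percentile 100. The random lists were drawn from all 21474 named protein-coding genes, detected or not. The housekeeping, S phase and ribosomal protein lists also lay at percentile 100, so a high percentile does not mark a lineage. The median of mast cells, basophils and eosinophils lay at percentile 99.98, that of megakaryocytes at 80.7 and that of stem and progenitor cells at 72.3. That of T and NK cells lay at 61.4 and that of liver and muscle at 16.8. Those of the B lineage, dendritic, and endothelial and stromal lists lay at percentiles 39.7, 43.7 and 45.7.

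The libraries ranked detected genes alike. Across the 3464 detected genes, which are not independent replicates, Pearson's r was 0.975 (95% bootstrap interval 0.971 to 0.979) and Spearman's rho 0.896 (0.887 to 0.905). Of these genes, 81.9% differed by less than 1.5 times and 95.1% by less than 2 times, after a filter that both libraries had to pass. Over the genes that passed in either library, an alternative chosen after seeing the data, these were 65.4% and 82.8%. The biological coefficient of variation was 33.5%. The shares of counts per gene differed by more than counting noise, with a chi-square statistic of 557497 on 11413 degrees of freedom, a test that takes reads as independent. Genes with very many reads weigh most in that statistic, among them Gm42418 with 5763926 and 6122182 expected counts. Spread was narrower at greater depth. The median absolute log2 ratio was 1.30 among the 2259 genes with a mean of 10 to 30 reads, against 0.30 from counting alone. It was 0.10 among the 208 genes with 3000 to 10000 reads, against 0.02. Of 5805 genes with a mean of at least 100 reads, 272 were over 2 times higher in replicate 2 and 156 in replicate 1.

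**Figure D2:**
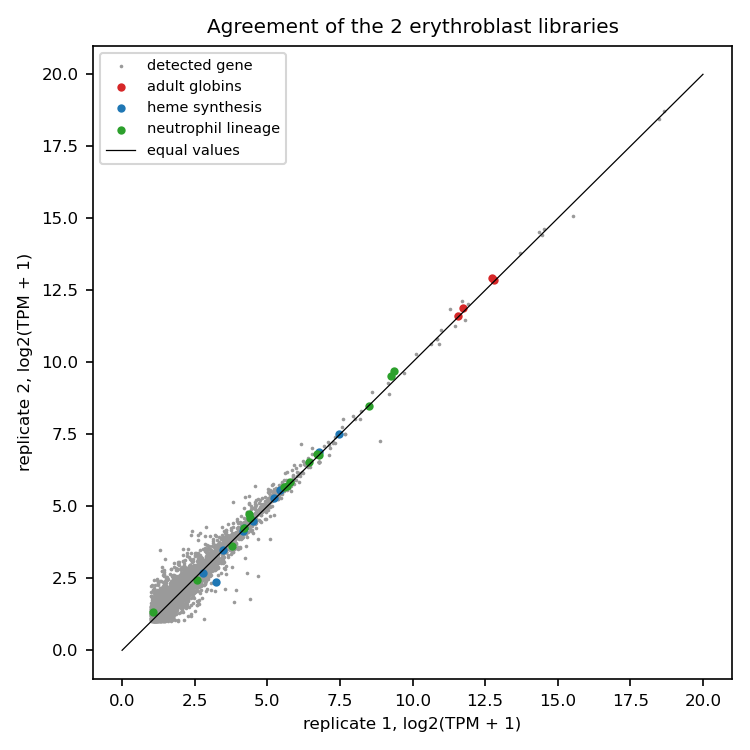
TPM of each of the 3464 detected genes in replicate 1 and replicate 2, both as log2(TPM + 1); coloured points are the adult globins, heme synthesis genes and neutrophil genes. Points close in on the line of equal values at higher expression, and Pearson's r across genes is 0.975.

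The 10 genes with the largest ratios between the libraries included pseudogenes, a histone and an interferon-inducible gene. The pseudogene Gm18853 had 278 expected counts in replicate 1 and 0 in replicate 2. Gm11518, also a pseudogene, had 202 and 20.3, Gm4070 769 and 165, Ifi207 248 and 54, and Cerkl 411 and 99.4. In the other direction, the intronic RNA Gm28967 had 0 and 302, the histone Hist2h3c1 0 and 215, Zfp760 9 and 226, Gtf3a 17.7 and 259.7, and Usp31 16 and 222. Where 1 library had 0, the other count was not whole: 278.2 for Gm18853, 302.1 for Gm28967 and 215.3 for Hist2h3c1. Such counts hold reads shared out among several places. A change in these genes cannot be told apart from a change in that sharing.

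Of 24 lists, 3 lay apart between the replicates, where chance puts 5% of lists outside the limits if their genes vary independently. The ribosomal protein list, taken by symbol, was higher in replicate 2, with a median log2 ratio of 0.09 at percentile 98.6 and 59 of 94 members higher. Cell cycle regulators were lower in replicate 2, with a median of -0.34 at percentile 1.51, and 4 of 12 members were higher there. Nuclear and structural noncoding RNAs were lower in replicate 2, with a median of -0.17 at percentile 1.39, and 2 of 6 members were higher there. Counts were simulated at the common coefficient of 33.5% for every gene. The members of each list were shifted by its distance from its random lists, 0.09, -0.35 and -0.14, in that order. These were called apart in 16%, 30% and 9.50% of runs. Spread in the data was narrower at greater depth, so a single coefficient overstates it for members with many reads. TPM was also used in place of TMM-scaled counts, which brings in a length correction and a pseudocount of 0.1 TPM for the prior count of 2. The cell cycle regulators (median -0.19) and the noncoding RNAs (median 0.00376) then no longer lay apart, and the histones did (median -0.05). The median of the random lists matched to the cell cycle regulators went from 0.00364 to 0.08, which left them at percentile 3.81. For the noncoding RNAs, at percentile 21.9, it went from -0.03 to 0.08, and for the histones from -0.01 to 0.11. Under TMM, the other lists ranged from percentile 3.48 for membrane and skeleton to 90.8 for the B lineage. The labels name no condition that separates the replicates, but the mean fragment length implied by the effective lengths was 136 bases in replicate 1 and 152 in replicate 2.

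Most of the 24 isoform genes had a clear leading transcript. The median share of a gene's TPM in its leader was 88.9 ± 0.815%, and some of the genes, such as Fech, Klf1 and Epor, have 1 annotated transcript. Slc4a1-201 held 99.9 ± 0.139% of Slc4a1 and Xpo7-201 held 99.5 ± 0.206% of Xpo7, both chosen after their values were seen. Epb41 spread over 18 transcripts, with Epb41-216 at 26.2 ± 0.766%, and Nfe2-205 led 10 transcripts of Nfe2 at 38.0 ± 2.15%. Kel-205, of 322 bases, held 57.7 ± 1.99% of the TPM of Kel, while Kel-201, of 2530 bases, led its expected counts at 64.5 ± 1.68%. Some leaders are annotated as noncoding. Tfrc-204, a retained intron transcript of 3527 bases, held 47.1 ± 0.0311% of Tfrc. Alas2-204, a processed transcript of 569 bases, held 53.4 ± 1.71% of Alas2, and the processed transcript Epb42-206, named after its value was seen, held 64.0 ± 0.675% of Epb42. The leader differed between replicates 1 and 2 for Pklr (Pklr-205 at 65.2%, Pklr-202 at 59.0%), Ank1 (Ank1-208 at 25.5%, Ank1-207 at 31.04%) and Slc11a2 (Slc11a2-201 at 41.4%, Slc11a2-205 at 68.4%). By expected counts, the same transcript led in both libraries for all 24 genes, though for Alas2 and Kel it was not the leader by TPM in either library.

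Over 2526 detected genes with more than 1 annotated transcript, 1906 had the same leader in both libraries, or 75.5% (95% Wilson interval 73.7% to 77.1%). The median leading share was 69.7 ± 0.847%.

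**Figure D3:**
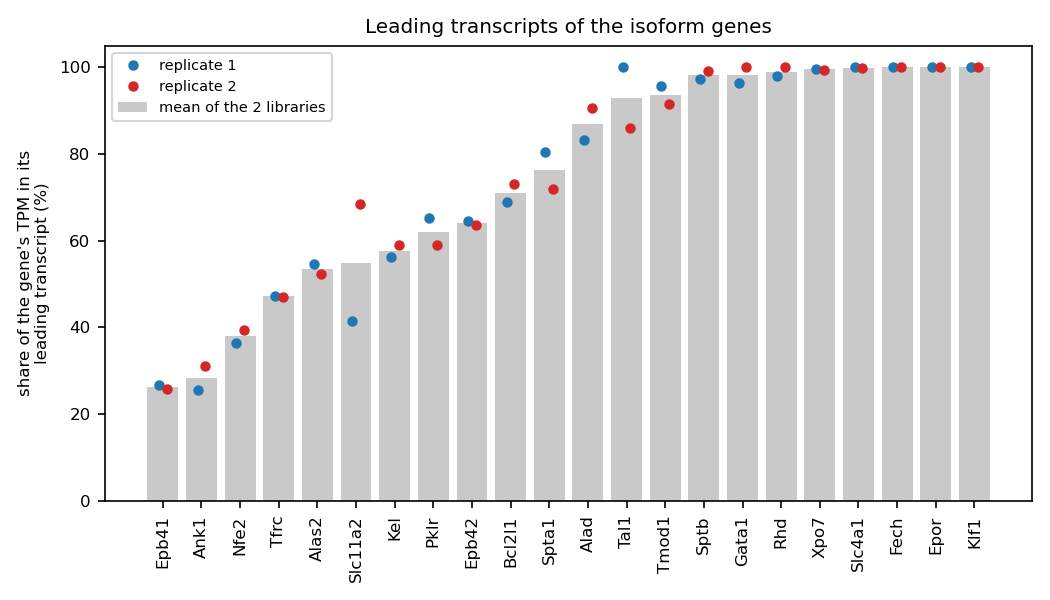
Share of a gene's TPM (percent) held by its leading transcript, for the isoform genes reported here; bars are the mean of the 2 libraries and the points are replicates 1 and 2. Shares run from 26.2 ± 0.766% for Epb41 to 100% for genes with 1 transcript, and the libraries lie farthest apart for Slc11a2.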

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

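Spike-in sequences, outside the gene measurement, drew 1790 expected counts in replicate 1 and 6408 in replicate 2, above the 3 counts that a count of 0 allows, or 0.00222% and 0.00548% of all counts.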

How the results depend on the processing

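No paired analysis was possible because there is 1 group. The nuclear protein-coding rescale, the removal of neutrophil and monocyte markers, and the alternatives for single genes were chosen after seeing the data. Against 3464, genes detected numbered 5358 at a TPM of 0.5 or more, 945 at 5 or more and 9988 by 10 or more expected counts. They numbered 6365 by the posterior mean and 9210 after the nuclear protein-coding rescale, which lowers the cut in deposited TPM. Pearson's r was 0.967 with a pseudocount of 0.1 and 0.958 with no filter, and Spearman's rho with no filter 0.833. Over genes detected in either library, chosen after seeing the data, 65.4% differed by less than 1.5 times and 82.8% by less than 2 times, since the filter on both libraries removes genes that disagree. The adult globin share was 16.3% over protein-coding genes, 17.1% without mitochondrial, rRNA and small RNA genes, 0.892% in counts scaled to the library total and 43.6% over nuclear protein-coding genes; a smaller denominator raises the share by construction. The alpha to beta log2 ratio was -0.26 in such counts. The erythroid over other-lineage log2 ratio was 5.16 over protein-coding genes, 3.39 with a pseudocount of 1, 3.58 with means of log2 values, 5.19 over nuclear protein-coding genes and 6.81 without neutrophil and monocyte markers. The leading share of isoform genes was 94.6% by expected counts and 73.6% at a TPM of 10 or more, that of detected genes 80.5% by expected counts, and the same transcript led in both libraries for 82.0% and 88.7% of detected genes under these settings. With TPM in place of TMM-scaled counts, 2 lists lay apart, 1 of them among the 3 above, and the median log2 ratio of nuclear and structural noncoding RNAs reversed from -0.17 to 0.00376. That list no longer lay apart, at percentile 21.9 of its matched random lists, whose median went from -0.03 to 0.08. That setting changes the length correction as well as the scaling. It also puts a pseudocount of 0.1 TPM in place of the prior count of 2 and matches the random lists on TPM. Except as stated, the cause was not tested. Each library alone gave 4011 to 4283 genes detected, an adult globin share of 2.04% to 2.22%, an embryonic share of 0.00249% to 0.00402%, an alpha to beta log2 ratio of -0.14 to -0.00295, an erythroid over other-lineage log2 ratio of 4.51 to 5.04, and leading shares of 88.3% to 89.5% for isoform genes and 69.1% to 70.3% for detected genes. The posterior mean moved 63 of 247 named genes by over 1 SD, a narrow limit with 2 libraries. It took Ptpn6 from 2.95 to 5.43 TPM, while the other genes that it moved by over 1.5 times had stood below a TPM of 0.1. Depth limits genes with few reads, whose spread between libraries was widest.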

Other observations

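Further gene groups were written down before their values were looked at, although Gapdh, Pgk1, B2m and Slc2a1 also stand in lists already seen. Of 10 genes of heme-regulated and stress translation control, 6 were detected. Ppp1r15a, which helps restore translation after stress, stood at 61.8 ± 6.82 TPM and the heme-sensing kinase Eif2ak1 at 18.8 ± 1.43 TPM, while the related kinases Eif2ak4 and Eif2ak3 stood at 0.265 ± 0.163 and 0.240 ± 0.141 TPM. Of 14 genes tied to chromatin structure and nuclear compaction, 6 were detected. Hmgn2 led at 48.7 ± 3.38 TPM, then Hmgb2 at 10.7 ± 0.721 TPM and the lamin B receptor Lbr at 10.3 ± 1.66 TPM, with Lmnb2 lowest at 0.255 ± 0.177 TPM. Chaperones were detected for 8 of 11 genes, led by Hspa8 at 33.9 ± 3.07 TPM and Hsp90aa1 at 12.3 ± 1.23 TPM, and Hspb1 had 0 counts in both libraries. Of 16 glycolysis genes, 10 were detected, led by Gapdh at 45.6 ± 2.38 TPM and Pgam1 at 8.36 ± 1.69 TPM. Of 13 genes of interferon response and antigen presentation, 11 were detected, with B2m at 84.2 ± 7.87 TPM and the class II genes Cd74 and H2-Aa at 8.72 ± 0.0566 and 5.50 ± 1.60 TPM.

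Among nuclear protein-coding genes outside the adult globins, S100a9, S100a8, Ngp, Pabpc1 and Gpx1 were the most abundant, a ranking chosen after the values were seen. Pabpc1, a poly(A)-binding protein, stood at 307 ± 10.1 TPM, Cd24a at 163 ± 5.78 TPM, Metap2 at 153 ± 12.04 TPM and Tmcc2 at 150.2 ± 1.83 TPM. The neutrophil list took 8.40 ± 0.268% of the TPM of nuclear protein-coding genes with adult globins left out. The retained intron transcript Hbb-bs-202, also singled out after its value was seen, held 73.9 ± 2.04% of Hbb-bs.

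Of the tests that follow, those on B lineage markers and on noncoding isoforms were chosen only after the result was seen. Neutrophil transcripts, led by S100a9 at 747 ± 118 TPM and S100a8 at 678 ± 88.0 TPM, may come from residual cells of that lineage or their RNA. Of 16 neutrophil genes outside the granule set, 0 of them in the other lists, 93.8% had at least 10 reads in both libraries. That limit is low: 9988 of all 43346 gene rows, noncoding types included, passed it. The share among protein-coding genes alone was not computed. Of the 16 genes, 9 reached a TPM of 1 in both libraries. The highest were Spi1 at 4.81 ± 2.31 TPM and Mmp9 at 4.79 ± 1.36 TPM, though Spi1 and others are also expressed by other myeloid cells. Whole marrow carried into both libraries cannot be told apart from residual cells of the neutrophil lineage. Of 13 B lineage markers, 23.1% had 10 reads in both, while immunoglobulin constant genes held 4060 and 6105 reads. The labels name no gate, expression by the erythroblasts themselves stays open, and no biological explanation was tested.

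Nuclear pseudogenes on chromosome 1 stood among the most abundant genes, for which reads shared with mitochondrial genes are a candidate explanation. The 5 unprocessed pseudogenes among the 40 most abundant genes matched mitochondrial transcripts at 99.8% identity or more over their best alignments. Gm29216, Gm28661 and Gm28437 stood at 22153 ± 1622, 3903 ± 829 and 3096 ± 797 TPM beside their matches mt-Co1, mt-Co2 and mt-Co3 at 24515 ± 929, 3199.6 ± 518 and 2642 ± 272 TPM. Gm10925 stood at 445 ± 79.0 TPM, below mt-Atp6 at 13659 ± 556 TPM, and Gm10222 at 3077 ± 221 TPM, above mt-Nd4l at 309.6 ± 221 TPM. Transcription of the nuclear copies stays open, and no biological explanation was tested.

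Noncoding isoforms led the TPM of Alas2, Tfrc and Epb42 in both libraries. Over all detected genes with several transcripts and the same leader in both libraries, 17.0% had a leader not typed as protein coding. No filter on gene type was applied, so that value is not a rate among protein-coding genes such as these 3. For Alas2, Tfrc and Epb42 as a set, length correction of short isoforms cannot be told apart from other sources. Of these 3 genes, 66.7% were still led by a noncoding isoform under expected counts. A protein-coding isoform led Alas2 at 61.4 ± 1.47% of counts. Tfrc and Epb42 kept their noncoding leaders, of 3527 and 1752 bases, at 56.2 ± 0.990% and 57.9 ± 0.971%. Expected counts are not divided by transcript length, but they share out reads between isoforms by an estimate. They thus cannot settle the source of the lead for single genes. Unspliced RNA and errors in sharing out reads stay open, and no biological explanation was tested.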
